A study of Mus musculus with 4 samples.

How the data were processed

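Tumour DNA from 4 Fah-/- Trp53-/- mice and a pool of liver DNA from 3 wild-type littermates were compared on 2-colour Agilent mouse CGH arrays. Per the labels, the tumour carried Cy5 and the pool Cy3 on every array, so no dye swap and no normal-against-normal array entered the analysis. Per the file headers, all 4 arrays lay on 1 slide in 1 scan, which leaves no slide or scan to test as a batch. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 12.0.0, and the file headers carry a later version number of the same software. The processed intensity of each colour was background-subtracted, detrended and linearly dye-normalised, per the file headers. The deposited log10 ratio is that of tumour over pool, and the authors' value table holds the same log10 ratio per spot, not centred, with column medians of 0.0023, 0.00233, 0.00131 and 0.000212. Raw mean and background intensity columns, per the file headers, are scanner brightness. Spot flags, per the file headers, mark outliers, saturation and signal above background.

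Each array had 180880 spots, of which 6575 were controls. Control spots and 95 to 120 spots flagged as outliers per array were left out, spots of a probe were averaged and log2 of tumour over pool processed signal was centred on the autosomal median, with no loess or quantile step. The noise between neighbouring probes had an SD of 0.25, 0.31, 0.34 and 0.35 in tumours 239, 240, 244 and 252, and 98.8% to 99.9% of spots were well above background in each colour. Of 170305 probes, 161460 were autosomal.

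Chromosomes were split by an own implementation of circular binary segmentation. A split was kept when its statistic passed the 99th percentile of the maxima over 200 draws of shuffled probes of the same array. Segments had at least 5 probes, neighbours closer than 0.1 were merged, and means of 0.2 or more and -0.2 or less were called gained and lost. A whole-chromosome call needed 80% of the chromosome's probes in called segments. Simulated shifts of 0.25 were recovered in 8 of 8 regions of 500 probes and 0 of 8 regions of 100. Shifts of 0.4 were recovered in 7 of 8 regions of 100 probes and 0 of 8 regions of 20. Between 18 and 58 unchanged probes were called per array. The simulation shuffled probe residuals over the genome, which removes regional trends and runs of low probes. It therefore says nothing about false calls that these may give. Lone outlying probes raise the threshold for keeping a split, so small regions with small shifts are missed.

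Bins of 1 Mb with at least 5 probes, and genes, were tested against 0 with limma 3.58.1 in R 4.3.3 (intercept only, Benjamini-Hochberg at 0.05). On simulated bins limma recovered 89 of 100 shifts of 0.4 and 19 of 100 shifts of 0.2, with 0 of 2338 unchanged bins called. The simulation took out each bin's mean over tumours and shuffled each tumour separately, which removes offsets shared by the arrays. It therefore says nothing about false calls that such shared offsets may give. Recurrence and gene lists were tested with 10000 circular shifts of each tumour's calls, and chromosomes with exact sign-flip permutation tests. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and hmmlearn 0.3.3. Plots used matplotlib 3.10.9.

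Of 18700 gene names in the files, 15443 matched a current symbol and 703 an older one in a RefSeq table of GRCm38.p6, which served only for names and gene order, and 2554 kept the files' name. Genes without probes were placed between flanking genes. The tests, gene lists and the rule for named genes were set before the data were examined. The rule named Fah and Trp53. It named list genes called the same way in 2 or more tumours or in a focal segment of large size, at most 30. It also named, for the 10 deepest focal segments and for up to 10 regions called in 3 or more tumours, their list genes or else the 3 genes with the largest mean on at least 3 probes. Genes with fewer than 3 probes took the covering segment's value. Tsc2, Runx3, Rptor, Hgd, Atr, Alad and Ighmbp2 were chosen after their values were seen.

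Alternatives covered the centring, background correction, the authors' value table, trend corrections, probe filter, call thresholds of 0.1 and 0.3, segment size, a 3-state hidden Markov model, focal size, bins of 5 Mb, robust limma and leaving out each tumour. A correction on probe and regional GC and the drawing in of lone outlying probes towards their neighbours were added after the data were seen. A correction on the GC content of the genome was not run, since no genome of the files' build was used here.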

Results

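Genomic DNA from liver tumours of 4 male-labelled Fah-/- Trp53-/- mice was measured by array comparative genomic hybridisation. Fah encodes fumarylacetoacetate hydrolase, the last enzyme of tyrosine breakdown, and Trp53 encodes the p53 tumour suppressor. Mice without Fah live on NTBC, a drug that blocks an earlier step of the same pathway. The labels give a full dose of 7.5 mg per L of drinking water and a reduced dose of 2.5% of it, taken for 6 months. Each tumour (239, 240, 244 and 252) was labelled with Cy5 and hybridised against the Cy3-labelled liver DNA of 3 pooled wild-type littermates. Each array gave 170305 probes, at a median spacing of 10.9 kb. Values are log2 ratios of tumour over pool, and positions are those of mm9. On an autosome of diploid cells, a single-copy gain in every cell would give 0.58 and a single-copy loss -1. The ploidy of the cells was not measured, and more copies per cell would make both levels smaller in size. These levels do not apply to X and Y, since the animals and the pool are labelled male. The number of arrays, 4, limits the precision, and the pool counts as 1 control sample, so the spread among control livers is left out of every test.

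The probes of the knocked-out genes were read first. The 2 Trp53 probes on chromosome 11 averaged 0.09, 0.08, 0.06 and 0.07 in tumours 239, 240, 244 and 252, with a mean of 0.07 ± 0.01 (SD, n = 4; limma adjusted p = 0.313). Under normexp background correction that mean was -0.13. The 2 Fah probes on chromosome 7 gave 0.30, 0.02, -0.19 and 0.05, with a mean of 0.04 ± 0.20 (SD, n = 4; limma adjusted p = 0.713), and -0.04 without tumour 239. The deleted parts of both genes are not given in the sources used here, so these probes check nothing about the genotype.

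The comparison of tumour with normal liver DNA asks which chromosomes were gained or lost. Chromosome 12 lay below 0 in 4 of 4 tumours, with mean log2 ratios of -0.40, -0.21, -0.39 and -0.24 in tumours 239, 240, 244 and 252, and was called lost along its length in all 4. Chromosome 15 lay above 0 in 4 of 4 tumours, at 0.23, 0.15, 0.35 and 0.28, and was called gained along its length in 239, 244 and 252. In tumour 240 it stayed below the calling threshold of 0.2. The means over tumours were -0.31 ± 0.10 for chromosome 12 and 0.25 ± 0.09 for chromosome 15 (SD, n = 4). An exact two-sided sign-flip permutation test gave p = 0.125 for each, the smallest value that 4 tumours allow, and an adjusted p of 0.278 over 20 chromosomes. Chromosome 12 of tumour 240 was no longer called lost when centred on its mode, at -0.195, on probes well above background or, like that of 252, with lone outlying probes drawn in or a threshold of 0.3. Chromosome 15 of tumour 239 was not called gained along its length with centring on the mode, normexp or lowess, at 0.21, 0.19 and 0.22, with outlying probes drawn in or, like that of 252, at a threshold of 0.3.

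**Figure D1:**
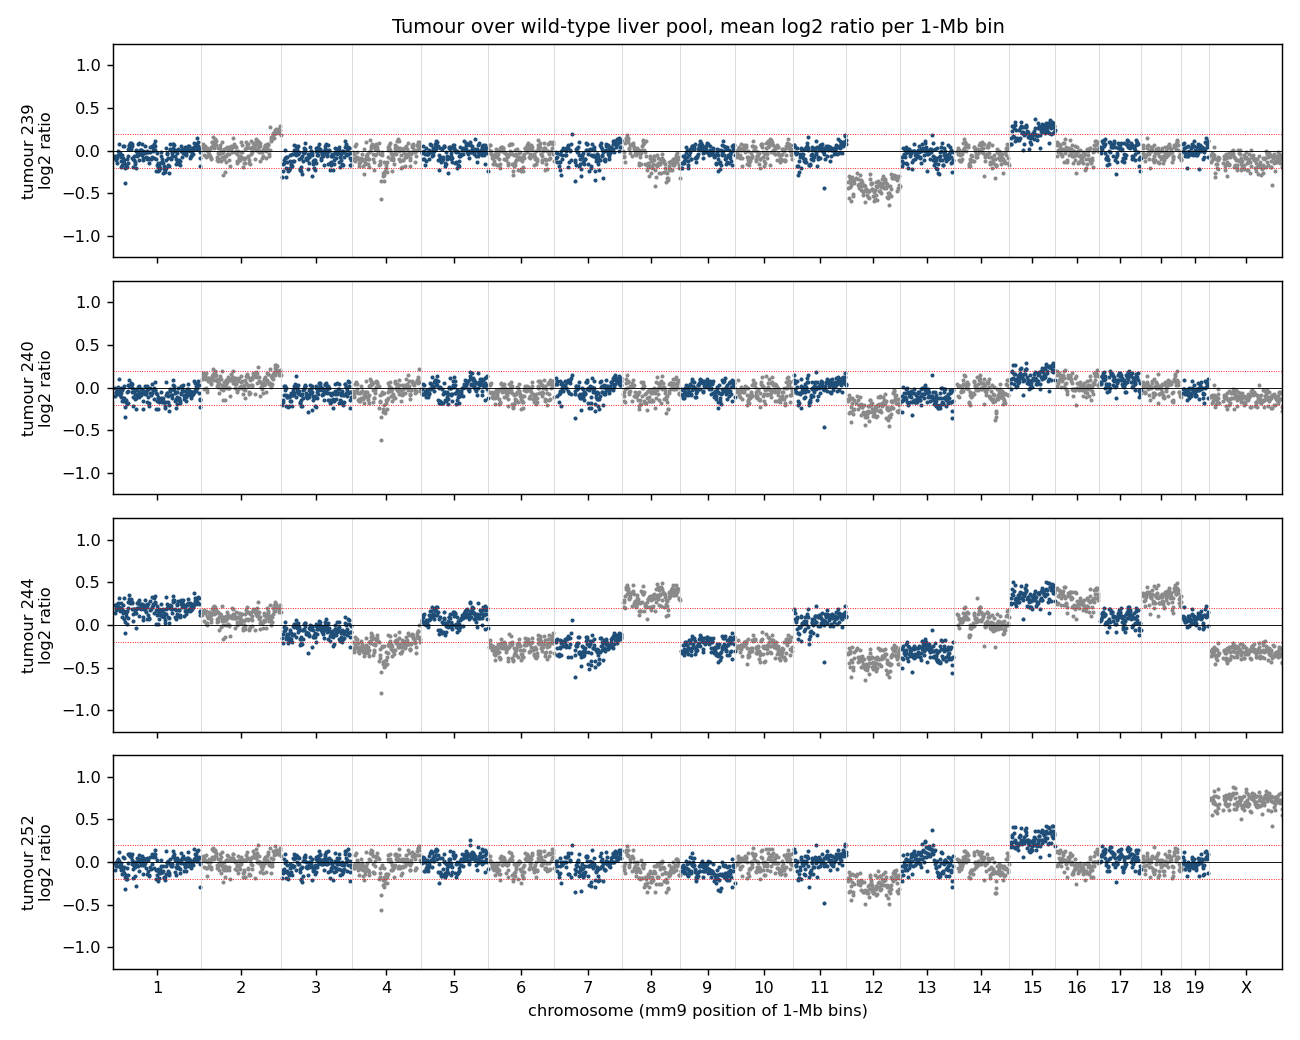
Mean log2 ratio of tumour over pool (vertical axis) in 1-Mb bins along chromosomes 1 to 19 and X (horizontal axis), 1 panel per tumour, with dotted lines at the calling thresholds of 0.2 and -0.2. Chromosome 12 lies low and chromosome 15 high in all 4 panels, and tumour 244 departs from 0 on many more chromosomes.

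The genes of the fixed lists that lay on chromosome 15 were Myc, an oncogenic transcription factor, Rictor, a subunit of the mTORC2 kinase complex, Rrm2b, a p53-inducible ribonucleotide reductase subunit, and Arid2, a chromatin remodelling subunit. On their own probes Rrm2b averaged 0.46 ± 0.13, Rictor 0.37 ± 0.09 and Arid2 0.36 ± 0.06 (SD, n = 4), with limma adjusted p of 0.00344, 0.00474 and 0.00413 over all genes. Their covering segments lay lower in every tumour, for Rrm2b at 0.24, 0.15, 0.34 and 0.28 in tumours 239, 240, 244 and 252. Probe effects that repeat between arrays, described below, are not part of the spread that limma used, so a gain beyond that of the chromosome is not shown. Under normexp Rrm2b averaged 0.25. Myc had no probe of its own and took the value of its covering segment, 0.25 ± 0.08, as placed between D030024E09Rik and Pvt1. On chromosome 12 the list genes were Mycn, Foxa1, a liver transcription factor, Gstz1, the tyrosine pathway enzyme just before Fah, and Akt1, a growth-signalling kinase. Mycn, Foxa1 and Gstz1 each took the covering segment's value of -0.31 ± 0.10, and Akt1 took -0.29 ± 0.07 (SD, n = 4). The 2 probes of Gstz1 averaged -0.70, but the single Akt1 probe averaged 0.23 (limma adjusted p = 0.0771) and the single Foxa1 probe -0.02, so single probes did not follow their segments. Ywhaq and Cpsf3, which were named for the region from 21000001 to 22000000, averaged -0.56 and -0.47 on 3 probes each, and Adam17 averaged -0.24 on 5. These genes were picked for the largest means in that region, which was 1 bin of the chromosome-wide loss. The region itself averaged -0.24 ± 0.08 (SD, n = 4), no lower than chromosome 12 as a whole, at -0.31. Adam17 lay at -0.57 under normexp, and did not pass without tumour 239, 240 or 244 (limma adjusted p = 0.0841, 0.067 and 0.0546).

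**Figure D2:**
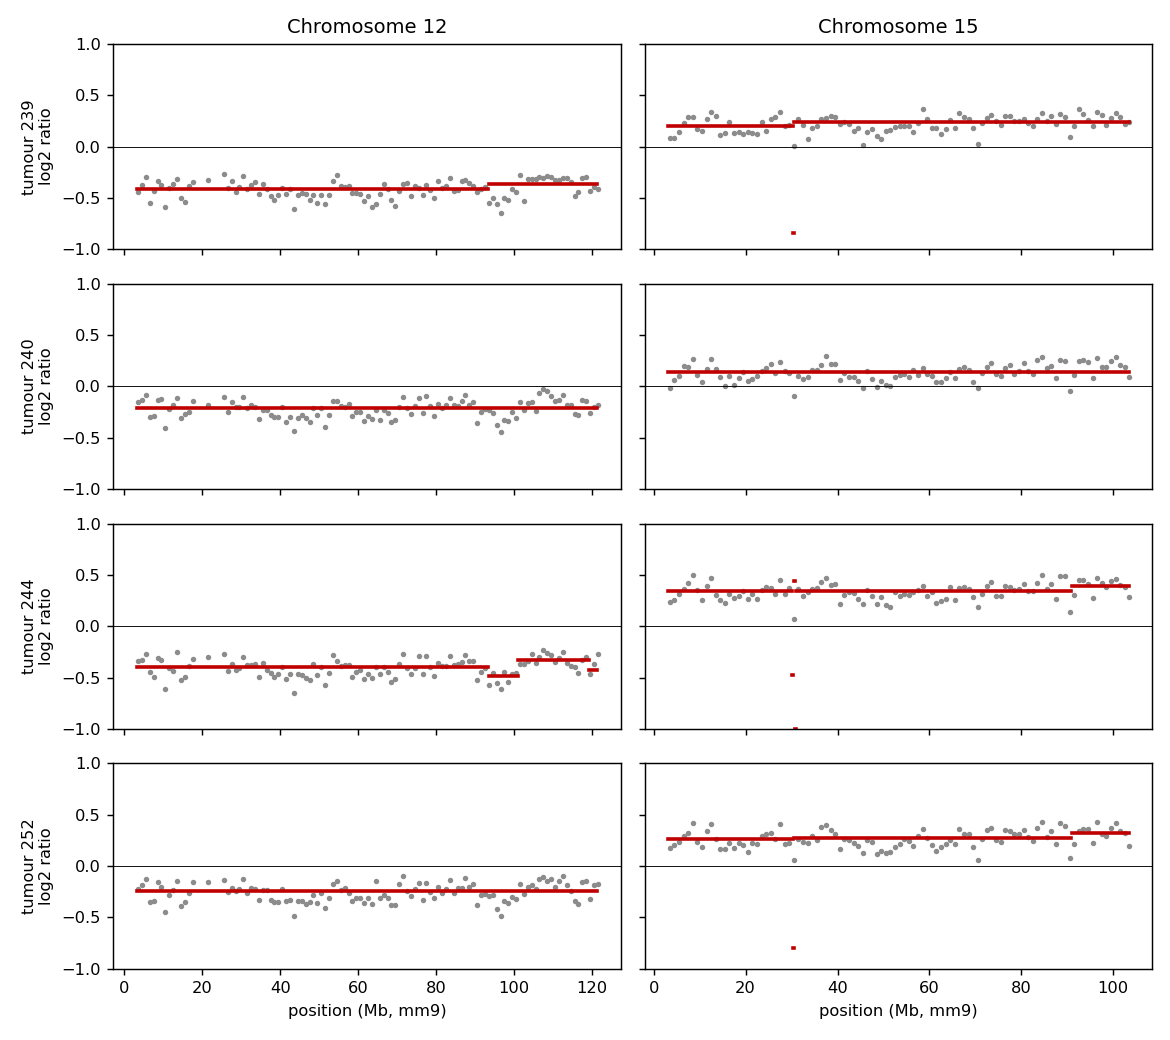
Log2 ratios of 1-Mb bins (grey points) and segment means (red lines) along chromosomes 12 and 15 by mm9 position, 1 row per tumour. The shift runs along the whole of both chromosomes, and the segment of chromosome 15 in tumour 240 lies at 0.15.

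Tumours differed widely in how much of the genome was altered. Gained segments covered 5.20%, 0.725%, 25.9% and 4.16% of the autosomes in tumours 239, 240, 244 and 252, a mean of 8.99% ± 11.4 (SD, n = 4). Lost segments covered 5.47%, 5.57%, 35.8% and 4.98%, a mean of 12.95% ± 15.2 (SD, n = 4). Tumour 244 alone showed gains of chromosomes 1, 8, 16 and 18, at 0.21, 0.33, 0.30 and 0.34, and losses of chromosomes 4, 6, 9, 10 and 13, at -0.23, -0.25, -0.23, -0.25 and -0.31, as well as of X, at -0.31, which some settings also called lost in 239 and 240. At a threshold of 0.1 chromosome 13 was also called lost in tumour 240, at -0.11. Over all tumours there were 8 whole-chromosome gains and 10 losses, of which 5 gains and 7 losses were in tumour 244. Without that tumour the means were 3.36% gained and 5.34% lost, with 3 gains and 3 losses. Its median was not its most frequent level: the mode lay 0.11 higher, and centring on the mode changed its shares to 13.2% gained and 39.3% lost and ended its gains of chromosomes 1 and 16, at 0.10 and 0.19. Chromosome 1 was also not called gained along its length under normexp, lowess, the hidden Markov model or with lone outlying probes drawn in. Chromosome 4 was not called lost with at least 10 probes per segment or outlying probes drawn in, and at a threshold of 0.3 the calls of chromosomes 1, 4, 6, 9 and 10 ended. Chromosome 7 of tumour 244, at -0.23, was not called lost along its length, but was with centring on the mode, normexp, lowess, the hidden Markov model and a threshold of 0.1. The lost share of tumour 240 was 0.189% with centring on the mode and 0.857% on probes well above background, and its gained share was 0% with normexp, lowess or GC correction and 0.00839% on probes well above background. In tumour 239 the gained share was 3.03% with centring on the mode or lowess and 1.05% with normexp, which gave a lost share of 8.99%.

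**Figure D3:**
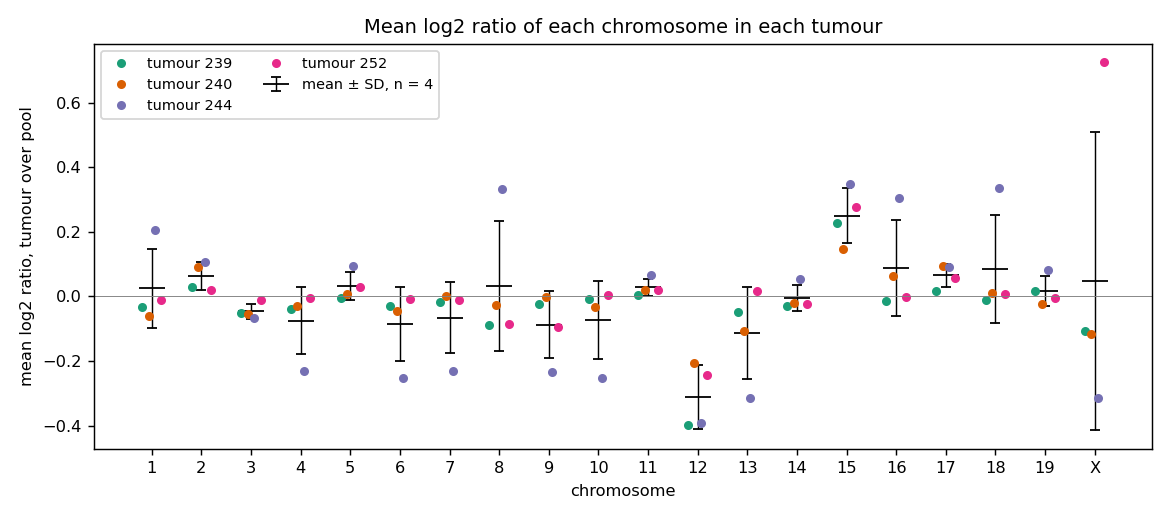
Mean log2 ratio (vertical axis) of chromosomes 1 to 19 and X (horizontal axis) in each tumour (coloured points), with the mean and SD over 4 tumours in black. Chromosome 12 lies below 0 and chromosome 15 above 0 in all 4 tumours, while X in tumour 252 lies at 0.72.

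The sex chromosomes of the tumour labelled 252 stood apart. Chromosome X had a median of 0.73 there and of -0.09, -0.11 and -0.30 in tumours 239, 240 and 244. Under normexp the means of X in these 3 were -0.33, -0.39 and -0.55, in place of -0.11, -0.12 and -0.31, and all were called lost. X was also called lost in 239 and 240 at a threshold of 0.1, and in 240 under lowess, at -0.23. The median of the 122 Y probes was -2.43 in 252, against -0.31, -0.14 and -1.20. All 4 animals and the pool are labelled male, so the gain of X counted for tumour 252 goes against its label.

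Single regions were then tested with limma across 2538 bins of 1 Mb. At an adjusted p below 0.05, 117 bins lay above 0 and 215 below. Chromosome 15 held 75 of the higher bins and chromosome 12 held 103 of the lower ones. A further 24 higher bins lay on chromosome 2, and chromosomes 3 and 4 held 31 and 18 lower bins. Chromosome 3 averaged only -0.05 ± 0.02 (SD, n = 4), and none of its probes lay in a called segment in any tumour. Small offsets common to the arrays can also pass limma, so these bins are not shown to be losses. Without tumour 239 no bin passed limma's adjusted threshold and 558 had an unadjusted p under 0.05. Without 240, 32 bins lay above and 65 below, without 252 these were 37 and 132, and without 244 they were 312 and 595. Gains shared by 3 or more tumours covered 117 bins, against a mean of 3.75 in 10000 circular shifts (one-sided permutation p = 0.0001, the smallest they can give), and 101 of these bins were on chromosome 15. The other 16 lay at the distal end of chromosome 2, where the region from 164000001 to 175000000 averaged 0.19 ± 0.04 (SD, n = 4) and held Aurka, a mitotic kinase, whose covering segment lay at 0.20, 0.20, 0.21 and 0.14 but whose single probe averaged -0.04. That segment's mean of 0.19 was 0.07 under normexp and 0.10 under lowess. Near the end of the chromosome Slco4a1 and Ntsr1 averaged 0.36 and 0.31 on their own probes, but 0.03 and 0.20 under normexp (limma adjusted p = 0.717 and 0.0278), and Slco4a1 also did not pass under lowess, at 0.20. The gain of distal chromosome 2 in 3 tumours lay near the threshold: no bin of chromosome 2 was shared with centring on the mode, normexp, lowess, GC correction, probes well above background, at least 10 probes per segment, the hidden Markov model or outlying probes drawn in, nor without tumour 239, 240 or 244. Shared losses covered 116 bins, against 6.90 in the shifts (one-sided permutation p = 0.0004), of which 113 were on chromosome 12 and were lost in all 4 tumours. The other 3 bins, on chromosome 4 from 77000001 to 80000000, averaged -0.23 ± 0.11 (SD, n = 4) and overlapped Ptprd, a receptor phosphatase gene, which averaged -0.28 ± 0.12 over 177 probes (limma adjusted p = 0.0157, and 0.0653 without tumour 240). Deep focal loci from 75901954 and 76677817, at means of -0.96 and -1.19 over the 4 tumours, lay in Ptprd but outside these bins. They enter the mean of Ptprd, which is therefore not a measure of these bins alone. No bin of chromosome 4 was lost in 3 tumours with centring on the mode, normexp, lowess, GC correction, probes well above background or the hidden Markov model, nor without tumour 239, 240 or 244. At a calling threshold of 0.3 neither direction had a shared bin, and normexp background correction gave 25 shared gained and 266 shared lost bins, 150 of the latter on X. The shifts treat the tumours as independent, but all arrays share the pool and the dye orientation. An offset common to the arrays can therefore also give shared bins and a small permutation p. Without 239 or 244 no bin was gained in all of the other 3 tumours, since 240 had no call on chromosome 15 and 252 none on distal chromosome 2.

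No focal gain of at most 10 Mb reached a mean of 1, but 43 focal segments over the 4 tumours had a mean of -1 or lower, 19 of them in tumour 244, which leaves 24 without it. They fell into 19 loci, and each locus averaged -0.5 or lower in all 4 tumours. The deepest, on chromosome 11 from 70989862 to 71107103, averaged -3.44, -3.44, -3.54 and -3.58 over 11 probes. It overlapped Nlrp1b, an inflammasome sensor, and the pseudogene Nlrp1c-ps, which averaged -2.82 and -3.49 on their own probes (-1.56 for Nlrp1b on probes well above background), and lay 1.65 Mb from Trp53. Loci on chromosome 9 from 117877147, on chromosome 4 from 66920371 and on chromosome 7 from 111393528 averaged -2.46, -1.87 and -1.04. The transcript ENSMUST00000035017 of the first averaged -1.64 on its own probes, but -0.66 on those well above background and -0.90 under normexp. The filter on background asks for both colours, so it can also drop probes whose tumour signal is low through a deep loss. The locus on chromosome 7 held genes of the Trim30 family, among them Trim30d, which averaged -0.27 on its own probes (limma adjusted p = 0.0583) and -0.15 without tumour 244. Trim30d passed under normexp, at -0.45, under lowess, at -0.36, and without tumour 252, at -0.31. Most loci were short: the one on chromosome 1 from 101036196 held 5 probes, of which 1 lay at -1 or lower in all 4 tumours. Focal gains numbered 1 with lowess, 2 on probes well above background and 4 with lone outlying probes drawn in. A hidden Markov model called 8 deep focal losses in place of 43, and segments of at least 10 probes gave 20.

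**Figure D4:**
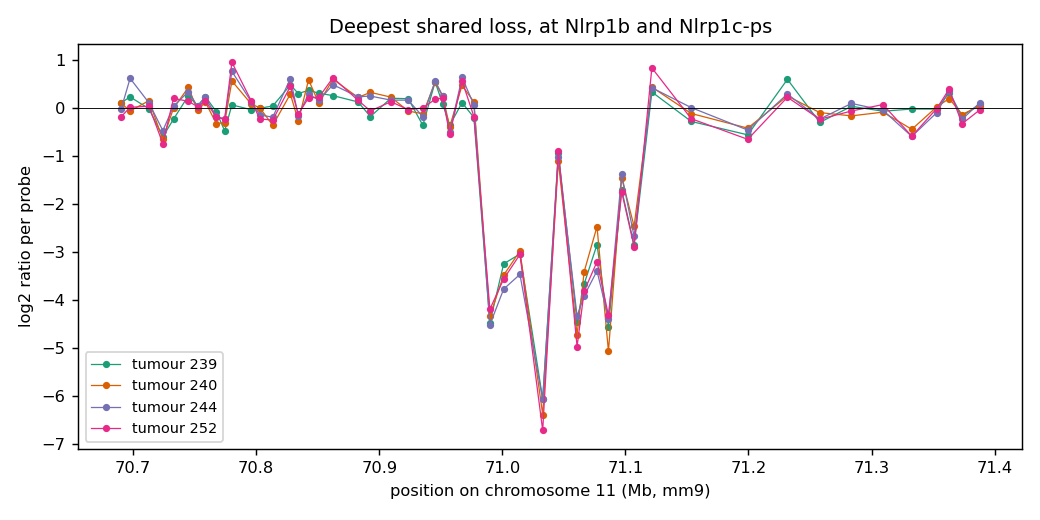
Log2 ratio of each probe (vertical axis) in each tumour (coloured lines) around the deepest shared loss on chromosome 11, by mm9 position (horizontal axis). The 4 tumours follow each other probe by probe, and the 11 probes of the locus average -3.44 to -3.58.

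None of the 9 gene lists was gained or lost more or less often than shifted genomes in 18 two-sided circular-shift permutation tests (lowest adjusted p = 0.292, for losses of tumour suppressors, fewer than in the shifts, which passed under 2 of the alternatives). Of the member-by-tumour pairs, oncogenes had 8 gained and 21 lost of 156, tumour suppressors 9 and 10 of 140, p53 targets and regulators 6 and 12 of 80, and tyrosine catabolism genes 2 and 7 of 32. NRF2 and oxidative stress genes had 4 gained and 4 lost of 48, mitotic checkpoint and DNA damage genes 4 and 5 of 72, mTOR pathway genes 4 and 6 of 52, hepatocyte genes 3 and 8 of 48, and strain copy-number genes 2 and 16 of 84. Most lost pairs were in tumour 244. Without it oncogenes had 6 lost pairs, tumour suppressors 1, tyrosine genes 3, mTOR pathway genes 3, hepatocyte genes 3, and p53, NRF2, mitotic and strain genes 0. Gained pairs without it were 4, 3, 0, 2 and 1 for the first 5 of these lists, and 2, 1, 2 and 0 for the other 4. In gene-level limma, 1 oncogene lay above 0 and 4 below over all genes, and 1 and 3 adjusted over the list alone. For tumour suppressors these were 4 and 1, then 3 and 1 adjusted over the list alone, with Tsc2 at 0.27 and Runx3 at 0.26. For p53 targets they were 4 and 4, then 4 and 5 adjusted over the list alone. For the mTOR pathway they were 4 and 1 both over all genes and adjusted over the list alone, with Rptor at 0.19. The tyrosine list had 0 and 2 (Hgd, at -0.31, and Gstz1), the NRF2 list 2 and 0, the mitotic list 1 and 2 (Atr at -0.33), the hepatocyte list 1 and 0 and the strain list 2 and 0, in each case with the same counts adjusted over the list alone. These gene-level calls include probe effects that repeat between arrays. Off chromosomes 12 and 15, 30.04% of 17367 genes passed limma's threshold, 41.8% of genes with 1 probe and 10.9% of those with 10 or more. Residuals of probes from their segments correlated at 0.72 to 0.86 between arrays across probes, which are not independent replicates. Antigen receptor loci, the markers of lymphocytes, were not analysed here: the only gene whose name fitted the rule was Ighmbp2, which is no receptor gene, and probes without a gene name were not assigned to loci.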

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

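The tests of both explanations for the sex chromosomes were chosen after the values were seen. Of 64 results tested for 1 tumour far from the other 3, 12 stood out, and chance alone marks about 1 in 20. In tumour 244, chromosomes 4, 6, 7 and 10 lay far below the others, at -0.23, -0.25, -0.23 and -0.25. Chromosomes 8, 14 and 18 lay above them there, at 0.33, 0.054 and 0.34, but with centring on the mode chromosome 14 turned to -0.056. The share of its autosomes that was lost, 35.8%, was far from 5.47%, 5.57% and 4.98%. Also in tumour 244, Trim30d, at -0.63, and the locus on chromosome 4 from 66920371, at -2.05, were lower than in the others. In tumour 252 the segment of Aurka, at 0.14, was lower and Cpsf3, at -0.33, was less far below 0 than in the others.

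Chromosomes X and Y of tumour 252, labelled male, lay at medians of 0.73 and -2.43. X was 1 unbroken segment, and its 17 blocks of 10 Mb lay between 0.68 and 0.78, so the blocks cannot tell the DNA of a female animal from a gain of the whole of X. A loss of Y and gain of X within the cells that lost chromosome 12 is argued against if the cells are diploid and lost a single copy. On that assumption, 31.1% of cells would carry the loss of chromosome 12. The Y median lay below the bound they allow by a difference of -1.90. Ploidy was not measured, so the share of cells is uncertain. A female animal, a sample of other origin and a sex-chromosome change in nearly all cells, apart from chromosome 12, stay open.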

How the results depend on the processing

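The corrections on probe GC, the restriction to chromosomes 1 to 19, the removal of shared focal segments and the drawing in of lone outlying probes were chosen after seeing the data; the correction on genome GC was not run. Over all alternatives, 2 values of the main results reversed and 37 moved past the bound set for their kind, while 159 stayed within it, which for the shares is an SD wide enough to hold large changes. The cause was not tested unless named. No paired analysis was possible because there was 1 group. Bins above 0 in limma numbered 71 with centring on the mode, 77 with normexp and 20 with bins of 5 Mb (fewer bins tested), and bins below 0 numbered 32 with the latter. Bins gained in 3 or more tumours numbered 74 with the mode, 25 with normexp, 74 with lowess on the reference signal, 67 with lone outlying probes drawn in and 0 at a threshold of 0.3. Bins lost in 3 or more numbered 266 with normexp, 288 at a threshold of 0.1 and 0 at 0.3. Whole-chromosome gains numbered 5 with the mode and 5 at 0.3, and losses 4 at 0.3. Mean shares of 5.29% gained and 12.5% lost with the mode, of 5.77% and 14.6% with normexp, of 11.2% and 18.6% at a threshold of 0.1 and of 4.40% and 4.08% at 0.3, stand beside 8.99% and 12.95%. Focal deep losses numbered 20 with at least 10 probes per segment, 8 with the hidden Markov model and 19 without focal segments called in all 4 tumours. Focal gains numbered 1 with lowess on the reference signal, 2 on probes well above background and 4, 1 in each tumour, with lone outlying probes drawn in. One list, losses of tumour suppressors (fewer than in shifted genomes), passed with lowess on the reference signal (1 list; adjusted permutation p = 0.018) and with at least 10 probes per segment (1 list; 0.0288). Trp53 probes reversed to -0.13 with normexp. Leaving out each tumour gave 0 to 312 bins above and 0 to 595 below 0, 0 to 101 bins gained in 3 or more tumours, 3 to 8 whole-chromosome gains, 3 to 9 losses, 24 to 38 focal deep losses, and -0.042 to 0.12 for the Fah probes, and shares of 3.36% to 11.7% gained and 5.34% to 15.6% lost. Chromosome 12 kept a mean below 0 and chromosome 15 above 0 under every scaling and without any 1 tumour, at -0.36 to -0.28 and 0.22 to 0.28. Of 170305 probes, 166942 were well above background on all arrays. On these alone, Nlrp1b averaged -1.56 in place of -2.82, and the lost share of tumour 240 was 0.857% in place of 5.57%. Both colours had to pass, so the filter can also drop probes whose tumour signal is low through a deep loss. Nlrp1b also has probes outside the deep locus, from 70967264 and 70976924, at 0.11 and -0.20 in tumour 239. The value of -1.56 therefore does not show a weaker loss.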

Other observations

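Of the tests below, that of dim probes and that of the GC trend were set before their results were seen, and the others after. The single probe of Alad, a haem synthesis gene on the list of genes whose copy number varies between mouse strains, averaged 1.20 over the 4 tumours (limma adjusted p = 0.000371), although its segment was not raised.

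A total of 1030 probes lay at -1 or lower in all 4 tumours. Separate deletions in each tumour are argued against for the deepest locus, on chromosome 11, where 4 of 4 tumours had the same first and last of its 11 probes. For the other 5 loci deep in 3 or more tumours the ends cannot tell: 3 had no more probes than the minimum of 5, which sets their ends, and of the other 2 only 1 had the same ends in 3 or more tumours. Their depth bears on it: all 19 deep focal loci averaged -0.5 or lower in all 4 tumours, and 0 did so in fewer. This held also for the 7 loci that were deep in 1 tumour only. Deletions acquired separately would not recur in every tumour at every locus, so these values argue against them for the 19 loci. Probe effects that repeat between arrays would recur in the same way and were not told apart from shared deletions. At the deepest locus 10 of 11 probes lay at -1 or lower in all 4 tumours. At others fewer did, such as 1 of 5 on chromosome 4 from 70603999. The median reference signal of the 1030 probes was at percentile 71.2 of all probes. Since they were chosen for a low ratio over that same signal, this test cannot decide whether dim probes are the cause. Of the 1030 probes, 957 were well above background on all arrays. Within 25 Mb of Trp53 or Fah there were 113 such probes against 46.8 in shifted genomes (one-sided permutation p = 0.0049), as inherited DNA linked to the knocked-out genes may give, but 89.0% lay farther away, which that linkage leaves without account. A difference in strain background between the tumour mice and the pool was not tested at these loci and stays open as a hypothesis. The list of strain copy-number genes did not depart from shifted genomes (circular-shift permutation test, adjusted p = 0.977 in each direction). Only 7 of its 21 members had probes of their own, so that list cannot decide.

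The distal part of chromosome 2, from 164000001, exceeded the rest of it by 0.21, 0.12, 0.11 and 0.12 in tumours 239, 240, 244 and 252. After correction on probe and regional GC these were 0.193, 0.103, 0.098 and 0.102, with SEs over probes of 0.009, 0.011, 0.011 and 0.012. Beforehand, 0.1 or more in 3 or more tumours was set as the bound that argues against a GC trend. Tumours 239, 240 and 252 met it, but 240 and 252 by less than their SE. A margin of the SE was applied that was not part of that bound, so a part for GC may remain. A common offset of the pool or the dyes cannot be told apart from a gain: tumour 239 differed by up to 7.01 standard errors over probes, but 3 of the 6 pairs of tumours did not differ beyond 3. These standard errors ignored that the same probes correlate between arrays, so they are too large for the differences. Probe noise also leaves out the spread between arrays. No biological explanation was tested.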
